A study of Mus musculus with 102 samples.

How the data were processed

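The series measured gene expression in epidermal stem cells taken from the epidermis of Per1-Venus BAC transgenic mice, which carry a fluorescent reporter of the clock gene Per1, on a C57B6/J background. It holds 53 arrays of adult and 49 of aged mice (Affymetrix mouse PM arrays), each of a single sample. Mice of 2 age groups (47 to 57 weeks, called adult, and 83 to 97 weeks, called aged) were given control diet ad libitum or calorie restriction (CR), a diet with 30% less food than the ad libitum intake. The diets ran for 25 weeks after an adaptation of 3 weeks in which the food of the restricted animals fell by 10% per week. Cells were collected at 6 zeitgeber times (ZT 0, 4, 8, 12, 16 and 20 h). Per the labels' protocols, cDNA was amplified from 25 ng of total RNA over 17 cycles, and 8 µg was labelled with biotin. Per the labels' protocols, the animals killed on a given day all belonged to the same time point, so the day of collection lies within the time point, and no label ties an array to a day.

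The deposited values are log2 expression levels made with RMA (background correction, quantile normalization and summary of each probe set), per the submitters' processing notes, which give no version. They were used as deposited. The table holds 45140 probe sets and values from 3.19 to 13.07. Medians of the arrays lay between 5.466 and 5.714, so no array was rescaled in the primary analysis. Of the probe sets, 28898 carried 1 gene symbol in the platform annotation, 551 carried several and 15691 carried none. Only those with 1 symbol were used, and 103 control probe sets were left out. Where a gene had several probe sets, the brightest over all arrays stood for it, which left 17097 genes. Genes whose mean was under the 30th percentile of all probe set means (4.735) were not tested, and 13383 remained. Levels are relative fluorescence on a log scale. The precision of a fold change depends on the number of arrays and on the spread between them, and probe sets near background understate the change.

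Daily rhythms were fitted per condition with limma 3.58.1 in R 4.3.3, as a cosine and a sine of 24 h with a moderated F test on 2 degrees of freedom. A gene was called rhythmic at a Benjamini-Hochberg adjusted p under 0.05. Amplitude is the distance from the mean to the peak of the fitted curve in log2 units, and peak time is in h of ZT. A further limma F test asked whether the fitted curve differed between conditions. Age and diet effects came from 1 limma model with a mean for each of the 24 groups of age, diet and time point, all arrays sharing 1 estimate of the spread. Each effect is the average of the differences at the 6 time points, so that unequal group sizes do not mix time with diet or age. The tests, 39 gene lists with 579 genes, the rule for naming genes and most of the alternatives were fixed before the data were examined. Of these genes 459 were tested, and 37 lists had at least 3 tested members. The other list genes, some core clock members among them, are not analysed here. List genes were matched by symbol and then by synonym, which put Pigq for Gpi1, Eno1b for Eno1 and Tom1l2 for Srebf1, although the fixed symbols name other genes. The list tests were therefore run again without these 3, a step chosen after the results had been seen, and the same 39 shifts and 22 enrichments passed. Shifts of a list were tested with camera at a preset inter-gene correlation of 0.01, and again with a correlation estimated from the residuals. Over 185 such tests, 39 passed with the preset correlation and 0 with the estimated correlation. Enrichment of rhythmic genes in a list was tested with Fisher's exact test, one-sided, over 148 tests. This test takes the genes as independent, which they are not, so its p values overstate the evidence. The average amplitude and the average phase of the core clock list were compared by permuting the arrays between conditions within each time point, two-sided, with 100000 resamples and a jackknife standard error. The comparison of the phase was added after the data had been seen.

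The genes named were chosen by a fixed rule. For age and diet effects it takes the 12 largest rises and the 12 largest falls among the genes past the threshold. For rhythms it takes the 12 largest amplitudes in each condition, and for the interaction and the rhythm differences the 12 smallest p values among those past the threshold. In every comparison it adds the core clock genes and, for each list past its test, the 4 members with the smallest p. Unnamed transcript symbols are left out. Where no gene passed, the 6 with the smallest p are named as not past the threshold.

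The tests were tested on simulated data, drawn from the residual spread of the real arrays with 200 genes changed in each of 10 draws over 13383 genes. A change of 0.60 was recovered for 97.4% of genes in the age effect on control diet, 97.6% in the diet effect in adult mice and 98.2% in the diet effect in aged mice. A change of 0.30 was recovered for 64.6%, 71.6% and 68.6% in the same comparisons. In the interaction, recovery was 37.8% for a change of 0.30 and 88.4% for 0.60. A difference of 0.30 between daily curves was recovered for 22.4% of genes by age on control diet. Under CR it was recovered for 31% in adult and 23.4% in aged mice. For a difference of 0.60 these values were 81.9%, 87.3% and 82.2%. An amplitude of 0.30 was recovered for 47.2% of genes in adult control, 65.7% in adult CR, 50.4% in aged control and 55.3% in aged CR. False calls were between 4.08% and 6.22% of all calls across the comparisons. The simulated genes were drawn independently of each other, unlike those of the real arrays, so this share does not measure the false calls in the real data.

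The alternatives fixed in advance were array medians set equal, a further quantile normalization, no filter on dim probe sets or a stricter filter, the mean of all probe sets of a gene, array weights, equal numbers of arrays per time group, other model forms, marker scores as covariates, a fold or amplitude minimum, the replicate number as a block, and each array left out in turn. Normal scores of the ranks were tested with an ordinary F test (190, 996, 728 and 624 rhythmic genes in adult control, adult CR, aged control and aged CR). This test was taken after the moderated one had been seen to give 0, 620, 0 and 0, since normal scores have the same total variance in every gene, which moderation then pools. Added after the data had been seen were a sex-linked score as a covariate, since the labels give no sex, array background as a covariate (the mean of the dim probe sets), the fit without the 10 arrays of highest background, and the fit without time point 0. Other tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Gene symbols and the neighbourhood of genes were checked against the annotation of assembly GRCm38.p6.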

Results

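Expression was measured in epidermal stem cells of mice on 53 arrays of adult and 49 arrays of aged mice, each of a single sample. The arrays fell into 4 conditions of age and diet: 23 of adult mice on control diet, 30 of adult mice under calorie restriction (CR), 24 of aged mice on control diet and 25 of aged mice under CR. Each condition was sampled at 6 zeitgeber times (ZT), with 3 to 6 arrays per time point. Values are log2 expression levels normalised by the authors with RMA, over 13383 tested genes, and their precision is limited by the number of arrays. The level of Xist, the transcript of the inactive X chromosome, exceeded the mean of Y-linked genes on 13 of 23 arrays of adult control and 18 of 30 of adult CR. It did so on 14 of 24 of aged control (1 of them by under 1 log2 unit) and 13 of 25 of aged CR. The sex is not given in the labels. Amplitudes and changes are in log2 units and are followed by their standard error (SE).

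In adult mice on control diet, genes of the molecular clock and of the cell cycle were enriched among the rhythmic genes. Per2 and Per3, repressors of the clock, peaked at ZT 12.6 (amplitude 1.07 ± 0.07) and ZT 11.8 (1.37 ± 0.12). The clock output factor Dbp peaked at ZT 10.7 (1.46 ± 0.12) and Nr1d2, a repressor of Arntl, at ZT 10 (0.97 ± 0.08). Arntl, the activator of the clock, peaked at the opposite phase, at ZT 23.3 (1.00 ± 0.18, adjusted p = 0.0117). Genes of DNA replication peaked near ZT 12, among them the helicase subunits Mcm2 (0.83 ± 0.10), Mcm3 (0.85 ± 0.10) and Mcm5 (0.84 ± 0.11). Genes of mitosis peaked around ZT 0, among them Top2a at ZT 23.5 (0.56 ± 0.10), Ube2c at ZT 0.6 (0.57 ± 0.09) and Cenpf at ZT 1.9 (0.65 ± 0.13).

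In this condition 156 of the 13383 genes were rhythmic (limma, 23 arrays), and 2144 had an unadjusted p under 0.05, where chance alone gives 669. Of these genes 37.8% peaked in the 4 h around ZT 0 and 41.7% in the 4 h around ZT 12. Among the genes of largest amplitude, those peaking near ZT 0 were Cldn4, a tight junction protein (1.22 ± 0.23), Itgb6, an epithelial integrin (1.06 ± 0.21), the epithelial transcription factor Ehf (1.06 ± 0.20), the phosphodiesterase Pde4b (0.97 ± 0.20) and the hair follicle factor Sox9 (0.97 ± 0.20). Cldn4, Itgb6, Ehf and Pde4b were higher at ZT 0 than the mean of the other times (2.47, 2.19, 1.98 and 2.05). A batch of the day of collection cannot be told apart from that time. The DNA repair enzyme Ung peaked at ZT 11.3 (0.99 ± 0.16). Sphk2, a sphingosine kinase, had the largest amplitude (2.12 ± 0.12, peak ZT 10.6), but the gene overlaps Dbp on chromosome 7 (assembly GRCm38.p6), so its signal could not be separated from that of its neighbour. Rhythmic genes were enriched among the core clock (10 of 16 genes, 14 adjusted over the list alone, Fisher's exact test, adjusted p = 3.86e-14) and DNA replication (10 of 19 genes, 17 adjusted over the list alone, adjusted p = 2.16e-13). Mitosis genes were enriched too (7 of 19, 12 adjusted over the list alone, adjusted p = 1.88e-08). So were genes of the unfolded protein response (6 of 16, 10 adjusted over the list alone, adjusted p = 2.45e-07), such as the chaperones Hsp90b1 (peak ZT 0.5) and Calr (peak ZT 23.3), and genes of DNA repair (3 of 21, 8 adjusted over the list alone, adjusted p = 0.0164). Fisher's test takes the genes of a list as independent, which they are not. The p values of these and the later enrichments therefore overstate the evidence. The count of rhythmic genes fell to 87 without replicate 2 of ZT 0, and to 95, 92 and 103 without replicate 2, 3 or 4 of ZT 12. A test of any difference among the 6 time points called 534 genes, and the fit with array background as a covariate called 481.

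In adult mice under CR, clock genes were among those of largest amplitude and peaked earlier in the day than on control diet. Dbp peaked at ZT 7.7 (1.87 ± 0.13), Per3 at ZT 9.2 (1.68 ± 0.08), Per2 at ZT 10.1 (1.15 ± 0.07), Nr1d2 at ZT 7.8 (1.03 ± 0.07) and Arntl at ZT 19.9 (1.43 ± 0.17). Tsc22d3 and Fkbp5, which glucocorticoids are known to induce, peaked at ZT 11.7 (1.16 ± 0.20) and ZT 12.7 (0.95 ± 0.22), while the glucocorticoid list did not pass its test (4 of 11 rhythmic, 4 adjusted over the list alone, adjusted p = 0.0569). Both genes were lower at ZT 0 than the mean of the other times (-2.87 ± 0.20 and -2.48 ± 0.25), which draws a fitted peak towards ZT 12. Genes of DNA replication peaked at about ZT 10, such as Gins2 (ZT 9.7, 0.53 ± 0.07) and Mcm3 (ZT 9.8, 0.69 ± 0.11), and those of mitosis later, such as Cdc20 (ZT 3.1, 0.53 ± 0.09) and Ccnb2 (ZT 2.3, 0.51 ± 0.11).

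Here 1082 genes were rhythmic (30 arrays, 3297 at an unadjusted p under 0.05), with a median amplitude of 0.269, and 49.3% peaked in the 4 h around ZT 8. Among the core clock 13 of 16 genes were rhythmic (14 adjusted over the list alone, adjusted p = 7.76e-11). Among DNA replication 11 of 19 were rhythmic (15 adjusted over the list alone, adjusted p = 5.09e-07), and among mitosis 8 of 19 (15 adjusted over the list alone, adjusted p = 0.000739). Of the DNA repair genes 6 of 21 were rhythmic (10 adjusted over the list alone, adjusted p = 0.0418), among them the checkpoint kinase Chek1 (peak ZT 9.6) and the damage sensor Atm (peak ZT 12.2). Of the unfolded protein response genes 5 of 16 were rhythmic (8 adjusted over the list alone, adjusted p = 0.0473), among them Herpud1 (peak ZT 11.6) and Calr (peak ZT 21). With rhythmic genes taken at an unadjusted p under 0.01, the enrichment was lost for DNA repair (adjusted p = 0.0549) and the unfolded protein response (adjusted p = 0.0545). Without the arrays of ZT 0 the count of rhythmic genes was 306, and with 3 arrays at each time point it was 296.

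In aged mice on control diet, genes of the clock and of the cell cycle were again enriched among the rhythmic genes. Per2 peaked at ZT 13 (0.97 ± 0.09), Per3 at ZT 12.1 (1.54 ± 0.17), Dbp at ZT 11.5 (1.49 ± 0.17) and Arntl at ZT 22.7 (0.95 ± 0.19). Replication genes peaked near ZT 12, such as Gins2 (ZT 11.9, 0.65 ± 0.09) and Mcm6 (ZT 11.2, 0.59 ± 0.08), and mitosis genes near ZT 4, such as Cenpf (ZT 4, 0.79 ± 0.13) and Ccnb2 (ZT 3.5, 0.78 ± 0.11). Insig1, a sensor of sterols that restrains cholesterol synthesis, peaked at ZT 2.9 (0.95 ± 0.20), Cldn4 at ZT 23.2 (1.31 ± 0.27) and Ung at ZT 13 (0.95 ± 0.19). Cldn4 was higher at ZT 0 than the mean of the other times (2.81 ± 0.50), which draws its fitted peak towards ZT 0.

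In these mice 750 genes were rhythmic (24 arrays, 3634 at an unadjusted p under 0.05), of which 36% peaked around ZT 12 and 24.1% around ZT 20. The calls took in 11 of 16 core clock genes (16 adjusted over the list alone, adjusted p = 1.33e-09) and 14 of 19 DNA replication genes (14 adjusted over the list alone, adjusted p = 1.18e-12). They also took in 13 of 19 mitosis genes (16 adjusted over the list alone, adjusted p = 3.57e-11) and 7 of 21 DNA repair genes (11 adjusted over the list alone, adjusted p = 0.00112), such as Chek1 (peak ZT 11.9) and Rad50 (peak ZT 11). The count depended on single arrays: it was 371, 426, 345 and 426 without replicate 1, 2, 3 or 4 of ZT 0, 438, 476 and 423 without replicate 2, 3 or 4 of ZT 12, and 373 and 423 without replicate 2 or 4 of ZT 16. It was 431 and 484 without replicate 2 or 4 of ZT 20, 427 and 394 without replicate 1 or 3 of ZT 8, and 1138 without replicate 2 of ZT 4. Without all arrays of ZT 0 it was 88.

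In aged mice under CR, clock genes peaked earlier than on control diet. Dbp peaked at ZT 7.5 (1.28 ± 0.10), Per3 at ZT 8.5 (1.45 ± 0.13), Per2 at ZT 9.6 (1.21 ± 0.08) and Arntl at ZT 20.2 (0.86 ± 0.19). Genes peaking near ZT 1 included Acsl4, which activates fatty acids (1.2 ± 0.17), Lmo7 (0.97 ± 0.16), Skil, a brake on TGF-beta signalling (0.94 ± 0.20), and the defensin Defb6 (0.94 ± 0.20), and the glucocorticoid-induced Tsc22d3 peaked at ZT 11.4 (1.11 ± 0.22). Cholesterol synthesis genes peaked near ZT 0, such as Idi1 (0.77 ± 0.15) and Sqle (0.85 ± 0.20), and glycolysis genes between ZT 12.8 and ZT 15.5, such as Pfkl (0.46 ± 0.10) and Tpi1 (0.37 ± 0.08).

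In this condition 652 genes were rhythmic (25 arrays, 2694 at an unadjusted p under 0.05), with 33.3% peaking around ZT 0 and 29.9% around ZT 12. Enrichment was found for the core clock (10 of 16 genes, 11 adjusted over the list alone, adjusted p = 7.99e-09) and DNA replication (11 of 19, 15 adjusted over the list alone, adjusted p = 3.78e-09). It was also found for mitosis (6 of 19, 13 adjusted over the list alone, adjusted p = 0.00217) and the unfolded protein response (4 of 16, 13 adjusted over the list alone, adjusted p = 0.0448). Glycolysis (4 of 14, 8 adjusted over the list alone, adjusted p = 0.0329, and 4 of 12, 8 adjusted over the list alone, adjusted p = 0.0176 without Pigq and Eno1b, which a synonym had brought in) and cholesterol synthesis (4 of 16, 7 adjusted over the list alone, adjusted p = 0.0448) passed as well. So did markers of bulge hair follicle stem cells (4 of 8, 4 adjusted over the list alone, adjusted p = 0.00329), namely Postn, Foxc1, Sox9 and Cxcl14. Targets of TGF-beta and BMP were the last (3 of 8, 3 adjusted over the list alone, adjusted p = 0.0418), namely Id1 (peak ZT 12.1), Id2 (peak ZT 11.8) and Skil, and this call was lost with rhythmic genes taken at an unadjusted p under 0.01 (adjusted p = 0.179). The count of rhythmic genes was 371, 422 and 388 without replicate 1, 3 or 5 of ZT 0, 987, 427 and 347 without replicate 1, 2 or 3 of ZT 12, and 410 and 364 without replicate 2 or 4 of ZT 16. Without all arrays of ZT 0 it was 221.

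**Figure D1:**
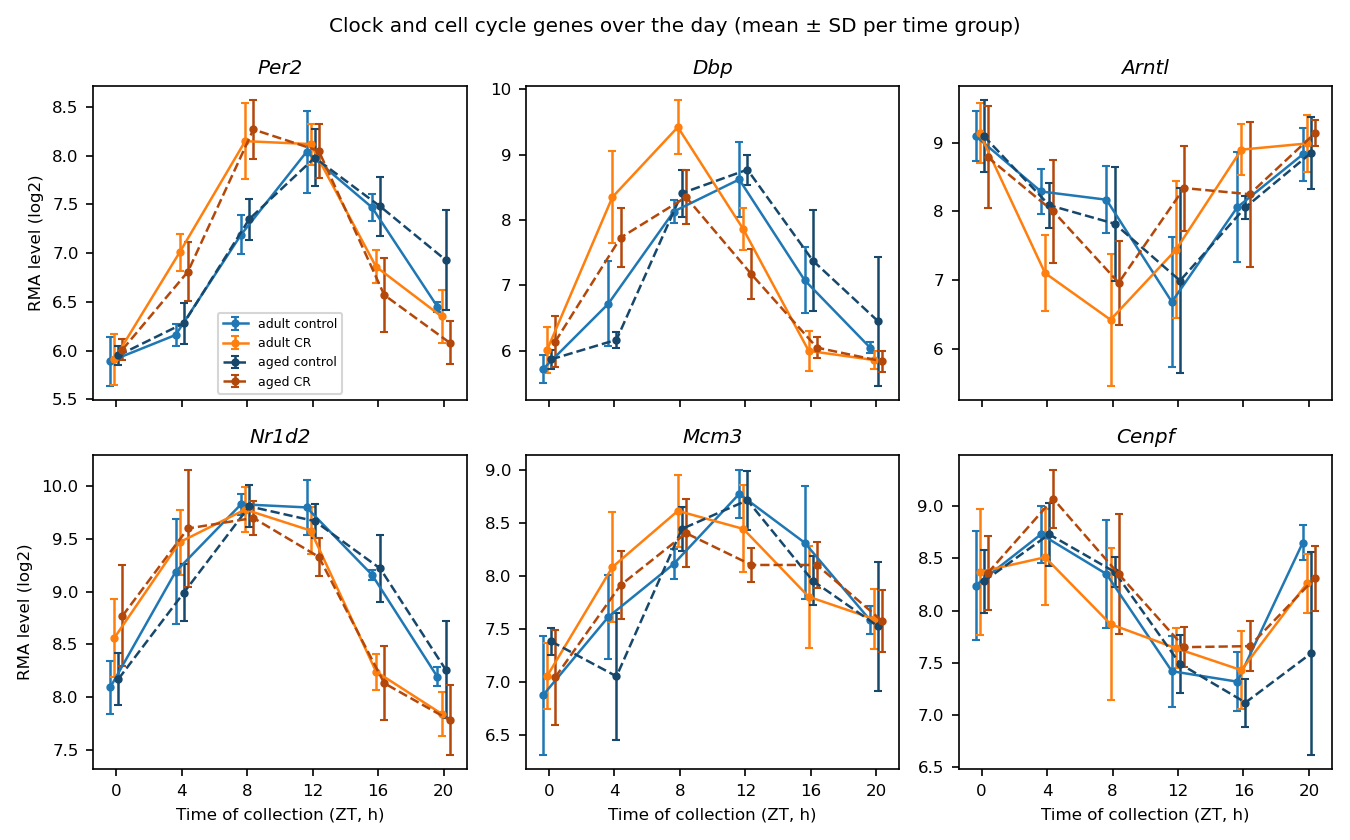
Mean log2 level (vertical axis) at each ZT in hours (horizontal axis) of 4 clock genes (Per2, Dbp, Arntl, Nr1d2), the replication gene Mcm3 and the mitosis gene Cenpf, with a line for each of the 4 conditions. Error bars are the standard deviation of the 3 to 6 arrays of each group. The curves of Per2 and Dbp under CR lie to the left of those on control diet.

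The same core of genes was called rhythmic in all conditions. In all 4 conditions 60 genes were called, of 1937 called in any. They held 10 core clock genes (Arntl, Npas2, Per2, Per3, Cry2, Nr1d2, Dbp, Tef, Hlf and Ciart) and, among the replication genes, Mcm2, Mcm3, Mcm4, Mcm5, Mcm6, Mcm7, Gins1, Gins2 and Prim1. Others, chosen after their values were seen, were the cyclins Ccnd1 and Ccnd2, the replication factors Pole2, Lig1 and Chaf1b, and the antioxidant enzyme Sod2. Adult control shared 96 rhythmic genes with adult CR, where independent lists would share 12.6, and 100 with aged control, where they would share 8.7. Aged control and aged CR shared 160 (36.5 for independent lists) and adult CR and aged CR shared 294 (52.7 for independent lists). Since each day of collection served a single time point, a batch of a day could be common to several conditions. Such a batch would add to the overlap, and the values for independent lists leave it out. The excess therefore cannot be put down to shared rhythms alone. How much of it such a batch could give was not tested.

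In the 3 pairs of conditions compared, the number of rhythmic genes did not differ by more than chance regrouping of arrays gave. Adult CR had 926 more rhythmic genes than adult control, and 19 of 100 assignments of the arrays to the diets within time points, the real one included, gave a difference as large. With all arrays in 1 fit the counts were 888 in adult control, 750 in adult CR, 725 in aged control and 998 in aged CR. The difference between aged and adult control was 594 (32 of 100 assignments) and that between aged CR and aged control was -98 (89 of 100). The core clock genes had mean amplitudes of 0.71 in adult control, 0.79 in adult CR, 0.68 in aged control and 0.66 in aged CR. None of these differed past the threshold, with 0.086 ± 0.033 for CR in adult mice (permutation test, two-sided, p = 0.22, adjusted p = 0.495), -0.012 ± 0.048 for CR in aged mice (p = 0.891) and -0.033 ± 0.045 for age on control diet (p = 0.552). For CR the permuted groups mix arrays of both diets, whose clock phases differ, so this p does not test the amplitude alone. The difference in adult mice was large against its SE, so a change of amplitude there stays open.

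**Figure D2:**
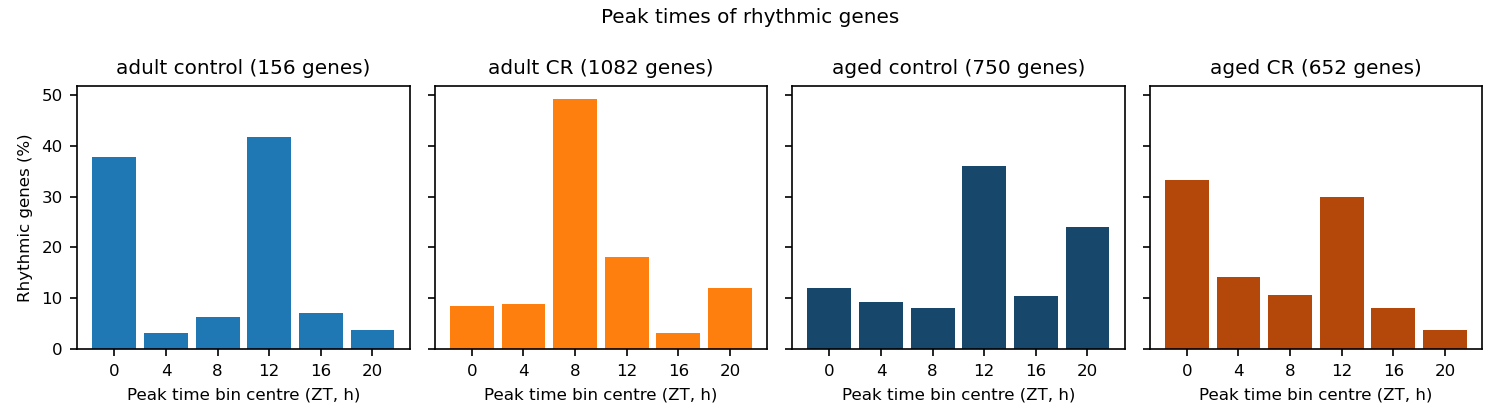
Share of the rhythmic genes of each condition (vertical axis, percent) that peak in each bin of 4 h (horizontal axis, centre of the bin as ZT in hours). Bars near ZT 0 and ZT 12 hold 37.8% and 41.7% of the rhythmic genes of adult control, and the bar at ZT 8 holds 49.3% of those of adult CR.

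Under CR the clock genes of the epidermal cells peaked earlier than on control diet at both ages. In adult mice Dbp peaked 3 h earlier, Per3 2.6 h, Per2 2.5 h, Tef 2.8 h, Nr1d2 2.2 h and Cry2 3.4 h. In aged mice Dbp peaked 4 h earlier, Per3 3.6 h, Per2 3.4 h, Tef 3.7 h, Nr1d2 3.3 h and Cry2 4.6 h. For these genes the fitted daily curve itself differed between the diets (limma F test, adjusted p from 4.93e-05 to 0.0112 in adult mice and from 2.43e-05 to 0.00261 in aged mice). Arntl, which peaked 3.4 h earlier in adult and 2.5 h earlier in aged mice, did not pass (adjusted p = 0.378 and 0.741).

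Across the 16 core clock genes the common shift was -2.79 h (SE 0.21) in adult mice and -3.48 h (SE 0.36) in aged mice, each with a permutation p of 1e-05, the smallest that 100000 resamples can give (two-sided, adjusted p = 4.5e-05). This summary of the phase was added after the data had been seen. The peak was earlier under CR for 14 of 16 genes in adult mice, Bhlhe40 and Rora being the exceptions, and for 16 of 16 in aged mice. The shift differed between the ages by -0.7 h (permutation p = 0.16). The replication genes shifted by -2.25 h (SE 0.7) in adult mice (permutation p = 0.00868, adjusted p = 0.026). In aged mice they shifted by -1.11 h (SE 0.7, permutation p = 0.211, adjusted p = 0.38). Mitosis genes shifted by 0.01 h (SE 0.96, permutation adjusted p = 0.994) in adult and -1.09 h (SE 0.99, adjusted p = 0.472) in aged mice.

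In adult mice 7 genes had a daily curve that differed between the diets (548 at an unadjusted p under 0.05, where chance alone gives 669): the 6 clock genes above and Sphk2. In aged mice 12 did (961 at an unadjusted p under 0.05), with the same 7 genes among them. The further ones included Cpt1a, Eci2 and Gpam, of which only Gpam was called rhythmic on both diets. Cpt1a, which carries fatty acids into mitochondria, had a fitted peak at ZT 15.9 on control diet (amplitude 0.20 ± 0.08, not called rhythmic, adjusted p = 0.201) and ZT 4.3 under CR (0.44 ± 0.08, difference of the curves adjusted p = 0.0138). Eci2, an enzyme of fatty acid oxidation, had fitted peaks at ZT 15.2 (0.36 ± 0.09, not called rhythmic, adjusted p = 0.0521) and ZT 6 (0.56 ± 0.11, difference of the curves adjusted p = 0.00804). Gpam, which starts the synthesis of triglycerides, peaked at ZT 14 and ZT 5.3 (adjusted p = 0.00333). Tmem269 moved from ZT 3 to ZT 21.7 (adjusted p = 0.0138). The count in aged mice was 19 without replicate 1 and 21 without replicate 4 of aged CR at ZT 12, 23 without replicate 5 of aged control at ZT 20, and 23 without all arrays of ZT 0.

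**Figure D3:**
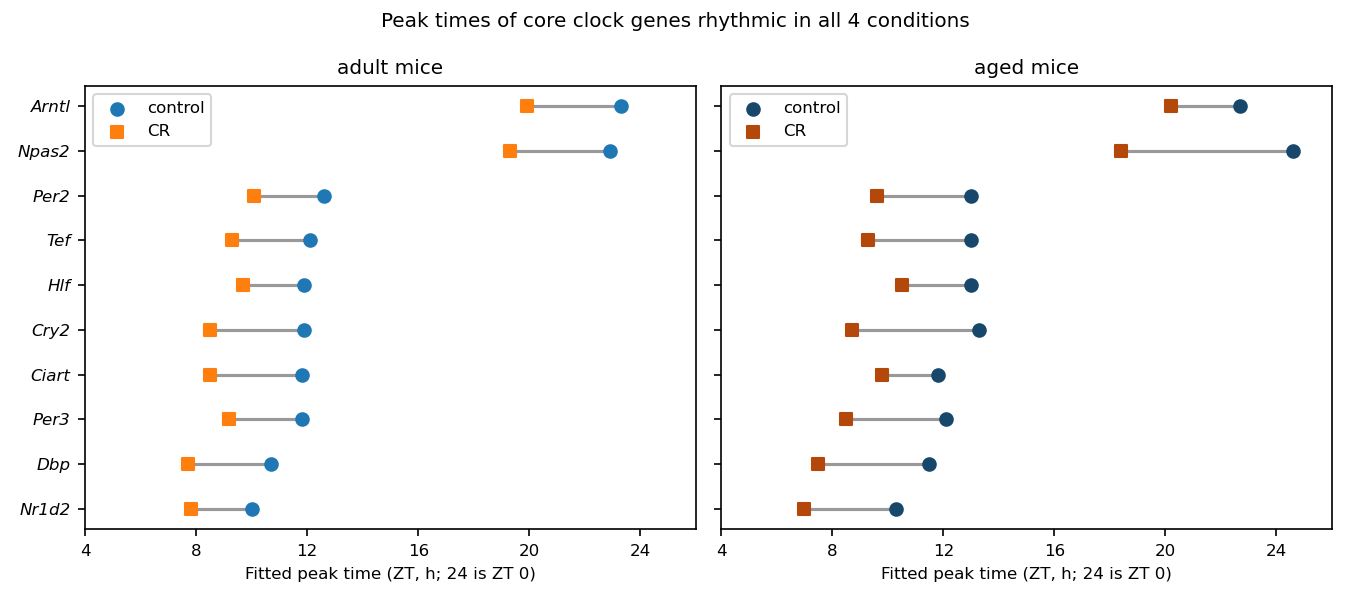
Fitted peak time (horizontal axis, ZT in hours) of the 10 core clock genes rhythmic in all 4 conditions (vertical axis), on control diet (circles) and under CR (squares), for each age. Dbp moves from ZT 10.7 to ZT 7.7 in adult mice and from ZT 11.5 to ZT 7.5 in aged mice.

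Between aged and adult mice on control diet no difference in daily curves was detected. The limma F test called 0 genes, with 159 at an unadjusted p under 0.05, where chance alone gives 669. Per2 peaked 0.4 h later in aged mice (adjusted p = 1), Dbp 0.9 h later and Cry2 1.4 h later. The common shift of the core clock was 0.49 h (SE 0.37, permutation p = 0.275, adjusted p = 0.413). Mitosis genes peaked 2.64 h later in aged mice (SE 0.86, permutation p = 0.0409), which did not pass over the family (adjusted p = 0.092), and replication genes differed by -0.05 h (SE 0.61). The genes with the smallest p, none past the threshold, were Rgcc, Vsig8, Cdca2, Aldh3a1, Ablim1 and Pou2f2.

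In adult mice, 43 genes rose and 31 fell under CR (30 arrays under CR against 23 on control diet). Col18a1, a collagen of basement membranes, fell by 0.72 (SE 0.10, adjusted p = 3.72e-06), Col6a1, a chain of collagen VI, by 0.67 (SE 0.14, adjusted p = 0.0055), the matrix protease Adamts1 by 0.64 (SE 0.17) and Npnt, a matrix ligand of integrins, by 0.52 (SE 0.09). Nrep fell by 0.89 (SE 0.18, adjusted p = 0.00251), and Dio2, which activates thyroid hormone, by 0.83 (SE 0.20). Acot1, a thioesterase of fatty acyl-CoA, rose by 0.50 (SE 0.12, adjusted p = 0.0265), Agpat4, an enzyme of phospholipid synthesis, by 0.44 (SE 0.08) and Crabp2, a carrier of retinoic acid, by 0.44 (SE 0.11). Psapl1 rose by 0.55 (SE 0.10, adjusted p = 0.000866), Ly6g6c by 0.48 (SE 0.11) and Pkib, an inhibitor of protein kinase A, by 0.47 (SE 0.08).

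The limma test called 74 genes, and 1337 had an unadjusted p under 0.05. Others of the largest rises were Spock2 (0.58), the interferon-induced Usp18 (0.54), Dlc1 (0.51), Fam117a (0.50), Septin5 (0.43) and Steap3 (0.43). The other large falls were Stfa3 (-0.77), the interferon-induced Ifi203 (-0.56), Bcar3 (-0.53), Tcim (-0.50), Thy1 (-0.49) and Ccdc3 (-0.49). The direction was the same at all 6 times for 22 of the 24 named genes past the threshold and at 5 of 6 for the others. In the list for fasting and fatty acid oxidation 9 of 10 genes were higher (camera adjusted p = 0.00694, and adjusted p = 0.487 with an estimated correlation), with 1 called (2 adjusted over the list alone) and Cpt1a at 0.21 and Plin2 at 0.20. The glycolysis list was lower for 13 of 14 (adjusted p = 4.87e-05, and adjusted p = 0.487 with an estimated correlation), with 0 called (0 adjusted over the list alone), among them Hk2 (-0.47 ± 0.17) and Slc2a1 (-0.14 ± 0.06). Of its members, Pigq and Eno1b were taken in by a synonym in place of Gpi1 and Eno1, and Pigq is no glycolysis gene. Without the 2, 12 of 12 were lower (adjusted p = 2.46e-05, and adjusted p = 0.448 with an estimated correlation). Epidermal differentiation genes were higher for 16 of 17 (adjusted p = 0.0177, and adjusted p = 0.487 with an estimated correlation), with 0 called (2 adjusted over the list alone), among them Sbsn (0.22 ± 0.07), Notch3 (0.29 ± 0.10) and Krtdap (0.34 ± 0.15).

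Genes of inflammation were lower for 10 of 14 (adjusted p = 0.00258, and adjusted p = 0.157 with an estimated correlation), none of them called over all genes or adjusted over the list alone, with Ptgs2 at -0.41 ± 0.16 and Il33 at -0.23 ± 0.10. For extracellular matrix and basement membrane the test pointed down (adjusted p = 0.00776, and adjusted p = 0.188 with an estimated correlation), with 6 of 10 genes lower, 0 called (2 adjusted over the list alone), Lamc1 at -0.18 ± 0.06 and Col4a1 at -0.23 ± 0.09. Fibroblast markers were lower for 6 of 7 (adjusted p = 0.00258, and adjusted p = 0.339 with an estimated correlation), of which Col6a1 alone was called (1 adjusted over the list alone). The fibroblast transcripts Col1a1 (-0.09 ± 0.08) and Dcn (-0.07 ± 0.07) did not pass. Their mean levels were low (5.83 and 6.04) and followed array background within groups (r = 0.772 and 0.857), so they say little about fibroblasts. T cell markers were lower for 9 of 10 (adjusted p = 0.0336, and adjusted p = 0.487 with an estimated correlation), with Thy1 alone called (1 adjusted over the list alone). Shifts were also found for mitosis (19 of 19 lower, median -0.107, adjusted p = 3.41e-05, and adjusted p = 0.62 with an estimated correlation) and ribosomal proteins (19 of 19 higher, median 0.056, adjusted p = 0.00258, and adjusted p = 0.66 with an estimated correlation). The same holds for the unfolded protein response (12 of 16 lower, adjusted p = 0.0197, and adjusted p = 0.636 with an estimated correlation) and oxidative phosphorylation (20 of 22 higher, adjusted p = 0.021, and adjusted p = 0.884 with an estimated correlation). In these lists 0 genes were called, and 0 adjusted over the list alone. The count of 74 was 40 and 37 without replicate 2 of adult CR at ZT 20 or replicate 1 at ZT 8, and 40, 46 and 42 without adult control replicate 4 of ZT 12, 3 of ZT 20 or 2 of ZT 8. Without all arrays of ZT 0 it was 38, with 32 of the 74 genes among them.

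In aged mice, 11 genes rose and 26 fell under CR (25 arrays under CR against 24 on control diet). Col6a1 fell by 1.06 (SE 0.15, adjusted p = 3.48e-06), Sparc, a matrix glycoprotein that binds collagen, by 0.43 (SE 0.09, adjusted p = 0.0138), Matn2, a matrix adaptor protein, by 0.47 (SE 0.12) and Sfrp1, a secreted antagonist of Wnt, by 0.44 (SE 0.07, adjusted p = 0.00035). Nrep fell by 0.85 (SE 0.18), Stfa3 by 0.81 (SE 0.16), Ccdc3 by 0.67 (SE 0.12), Thy1 by 0.59 (SE 0.13) and Ppic by 0.52 (SE 0.09, adjusted p = 0.000765). Ly6g6c rose by 0.53 (SE 0.11, adjusted p = 0.00967), Plaat3, a phospholipase, by 0.43 (SE 0.09) and the tyrosine kinase Tec by 0.41 (SE 0.07, adjusted p = 0.00134). Zfp750, a driver of keratinocyte differentiation, rose by 0.28 (SE 0.07) and the epidermal keratin Krt80 by 0.24 (SE 0.05).

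The test called 37 genes, with 698 at an unadjusted p under 0.05, where chance alone gives 669. The other rises were Ank (0.40), Amotl2 (0.33), Camsap3 (0.32), Pgap4 (0.30), Rhbdf2 (0.26) and Abcb10 (0.19), and further falls were Tcim (-0.52), Ifi203 (-0.47) and Olfm1 (-0.44). The direction was the same at all 6 times for 20 of the 24 named genes past the threshold and at 5 of 6 for the others. Markers of Langerhans cells and macrophages were lower for 8 of 9 (adjusted p = 6.18e-06, and adjusted p = 0.157 with an estimated correlation), with 0 called over all genes and 3 lower adjusted over the list alone. These include the antigen presentation genes H2-Eb1 (-0.28 ± 0.07), Cd74 (-0.28 ± 0.08) and H2-Ab1 (-0.54 ± 0.19). The fibroblast list was lower (adjusted p = 0.00036, and adjusted p = 0.232 with an estimated correlation), with Col6a1 and Sparc called (2 adjusted over the list alone) and Dcn at 0.04 ± 0.07 and Col5a1 at -0.04 ± 0.06. Bulge markers were lower for 5 of 8 (adjusted p = 0.0485, and adjusted p = 0.467 with an estimated correlation), with Npnt called (-0.43 ± 0.10, 2 adjusted over the list alone) and Sox9 at 0.30 ± 0.17.

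Epidermal differentiation genes were higher for 15 of 17 in aged mice too (adjusted p = 0.00222, and adjusted p = 0.331 with an estimated correlation), with 0 called (1 adjusted over the list alone), among them Sbsn (0.25 ± 0.07) and Grhl3 (0.30 ± 0.12). The glycolysis list was lower for 13 of 14 (adjusted p = 0.000214, and adjusted p = 0.487 with an estimated correlation), among them Pkm (-0.15 ± 0.06). Without Pigq and Eno1b it was lower for 12 of 12 (adjusted p = 0.000118, and adjusted p = 0.478 with an estimated correlation). The fatty acid synthesis list was higher for 11 of 15 (adjusted p = 0.00339, and adjusted p = 0.157 with an estimated correlation), among them Me1 (0.20 ± 0.07) and Acly (0.14 ± 0.06). Without Tom1l2, an unrelated gene taken in by a synonym in place of Srebf1, it was higher for 10 of 14 (adjusted p = 0.00551, and adjusted p = 0.144 with an estimated correlation). Cholesterol synthesis genes were higher for 13 of 16 (adjusted p = 0.0341, and adjusted p = 0.814 with an estimated correlation), among them Hmgcs1 (0.37 ± 0.17). Oxidative stress defence was lower for 12 of 14 (adjusted p = 0.00292, and adjusted p = 0.331 with an estimated correlation), among them Gstm1 (-0.16 ± 0.07). The core clock was lower for 12 of 16 (adjusted p = 0.00551, and adjusted p = 0.339 with an estimated correlation). Mitosis genes were higher for 19 of 19 (median 0.113, adjusted p = 6.18e-06, and adjusted p = 0.56 with an estimated correlation), among them Cenpf (0.30 ± 0.12). In these lists, other than epidermal differentiation, 0 genes were called, and 0 adjusted over the list alone. The count of 37 was 24 without aged CR replicate 1 of ZT 4, and 24 and 22 without aged control replicate 4 of ZT 16 or 3 of ZT 8. Without all arrays of ZT 0 it was 57, with 27 of the 37 genes among them.

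**Figure D4:**
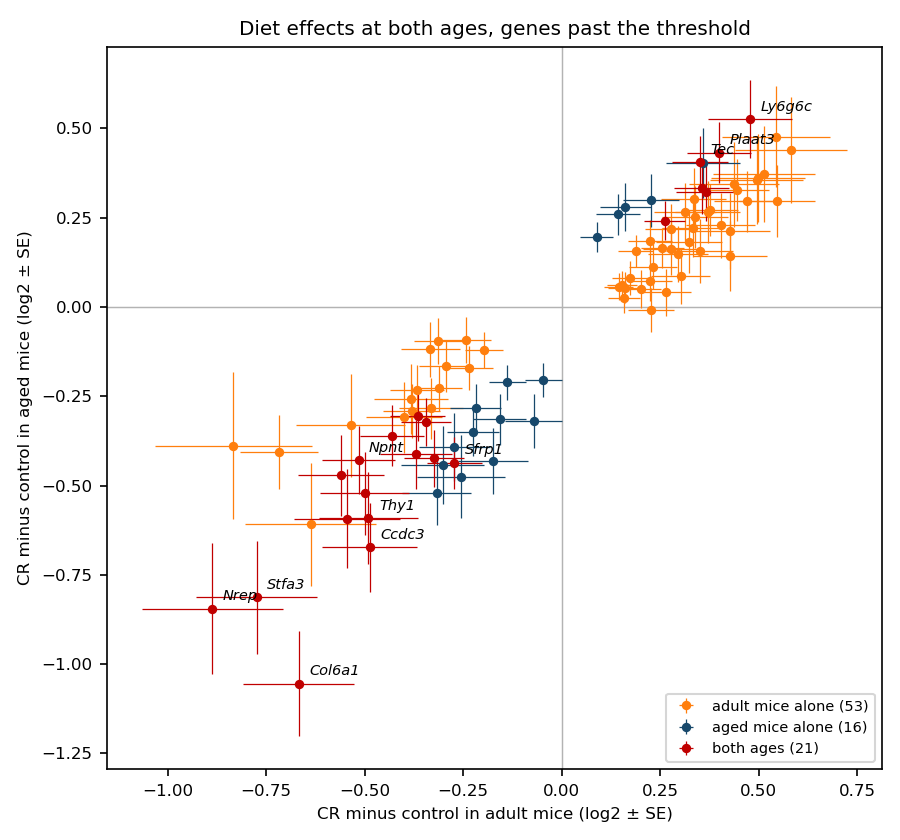
Change under CR (log2, CR minus control) in adult mice (horizontal axis) against that in aged mice (vertical axis) for the genes called at either age, with bars of SE in both directions. Colours mark the 53 genes called in adult mice alone, the 16 called in aged mice alone and the 21 called at both ages, Col6a1 being the lowest in aged mice.

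The diet effects of adult and aged mice had genes in common. Past the threshold at both ages were 6 genes higher under CR (Amotl2, Camsap3, Krt80, Ly6g6c, Plaat3 and Tec), where independent lists would share 0.035 (Fisher's exact test, one-sided, p = 3.49e-13). The genes lower at both ages numbered 15, where independent lists would share 0.06 (Fisher's exact test, one-sided, p = 3.82e-35). They included Col6a1, Npnt, Sfrp1, Nrep, Stfa3, Ccdc3, Thy1, Tcim and Ifi203, and, chosen after their values were seen, the cadherin Cdh4, the neurotrophin receptor Ntrk2, the carbonic anhydrase Car12 and the collagen-binding receptor Antxr2. These Fisher tests take the genes as independent, which they are not, so their p values overstate the evidence. With each age fitted on its own arrays, 5 genes higher and 12 genes lower under CR were shared. Of the 74 genes called in adult mice 73 had the same sign in aged mice, and of the 37 called in aged mice 37 had the same sign in adult mice. Across all tested genes, which are not independent replicates, the effects correlated with r = 0.47 (rho = 0.291, jackknife SE 0.25), inside the range of 100 simulations of unchanged groups (-0.578 to 0.566), and r was 0.203 without the 10 arrays of highest background.

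On control diet, the daily mean of no single gene was found to differ between the ages. In limma, 0 of 13383 genes passed between 24 aged and 23 adult arrays, and 171 had an unadjusted p under 0.05, where chance alone gives 669. The genes with the smallest p, none past the threshold, were Cadps2, which primes secretory vesicles (0.54 ± 0.11, higher at 6 of 6 times, adjusted p = 0.095), and the lysosomal glycoprotein Gpnmb (0.38 ± 0.10). They were followed by the cell cycle regulator Rgcc (-0.55 ± 0.15), the BMP and Wnt antagonist Sostdc1 (-0.40 ± 0.11), Fbp2 (0.23 ± 0.07) and Wnt2 (0.26 ± 0.08). Bulge markers were lower in aged mice for 8 of 8 (median -0.108, adjusted p = 0.000374, and adjusted p = 0.157 with an estimated correlation), with Foxc1 at -0.18 ± 0.11 and Postn at -0.23 ± 0.15. Mitosis genes were lower for 18 of 19 (median -0.129, adjusted p = 5.48e-10, and adjusted p = 0.371 with an estimated correlation), with Tpx2 at -0.18 ± 0.10 and Cenpf at -0.19 ± 0.12. Ribosomal protein genes were higher for 16 of 19 (median 0.023, adjusted p = 0.0175, and adjusted p = 0.814 with an estimated correlation). In these lists 0 genes were called, and 0 adjusted over the list alone. The core clock genes differed by -0.14 to 0.15, none past the threshold. The count was 1 without replicate 1 of aged CR at ZT 16, replicate 2 of aged control at ZT 4, or replicate 3 or 4 of adult control at ZT 0.

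The age effect and the effect of CR in aged mice were compared across genes, which are not independent replicates, to ask whether genes that differ with age move the other way under CR. The correlation was r = -0.226 (jackknife SE 0.165), but the aged controls enter both effects with opposite sign. Unchanged groups gave a mean of -0.434 over 100 simulations (-0.811 to 0.274). With the aged controls divided between the effects by odd and even replicate number, r was 0.242 and 0.181.

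Under CR, aged mice had lower levels of 3 genes than adult mice (25 against 30 arrays). Rgcc fell by 0.76 (SE 0.14, adjusted p = 0.0128, lower at 5 of 6 times), Sostdc1 by 0.51 (SE 0.11, adjusted p = 0.0349) and Pdlim4, an actin-associated protein, by 0.46 (SE 0.09, adjusted p = 0.0149), these last at 6 of 6 times. Langerhans cell and macrophage markers were lower for 8 of 9 (adjusted p = 1.6e-06, and adjusted p = 0.157 with an estimated correlation), with 0 called over all genes and 5 lower adjusted over the list alone. They were led by H2-Ab1 (-0.78 ± 0.18, adjusted p = 0.0712) and H2-Eb1 (-0.29 ± 0.07, adjusted p = 0.0776). Cholesterol synthesis genes were higher for 15 of 16 (median 0.166, adjusted p = 3.17e-08, and adjusted p = 0.188 with an estimated correlation), with Idi1 at 0.40 ± 0.15 and Sqle at 0.41 ± 0.19 and 0 called (0 adjusted over the list alone). Inflammation genes were higher for 12 of 14 (adjusted p = 0.00447, and adjusted p = 0.157 with an estimated correlation), with Ptgs2 at 0.52 ± 0.16 and 0 called (1 adjusted over the list alone). Bulge markers were lower for 7 of 8 (adjusted p = 0.0113, and adjusted p = 0.285 with an estimated correlation), with Postn at -0.50 ± 0.14 and 0 called (1 adjusted over the list alone).

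Mitosis genes were higher in aged than adult mice under CR for 18 of 19 (median 0.104, adjusted p = 1.6e-06, and adjusted p = 0.487 with an estimated correlation), with Aurkb at 0.36 ± 0.14. Ribosomal proteins were lower (18 of 19, adjusted p = 0.000637, and adjusted p = 0.572 with an estimated correlation). So were oxidative phosphorylation (20 of 22, adjusted p = 0.0168, and adjusted p = 0.867 with an estimated correlation) and autophagy and lysosome genes (18 of 20, adjusted p = 0.017, and adjusted p = 0.654 with an estimated correlation). In these lists 0 genes were called, and 0 adjusted over the list alone. At an unadjusted p under 0.05 the test gave 732 genes, where chance alone gives 669. The count of 3 was 0 without the arrays of ZT 0 or without aged CR replicate 3 of ZT 4, and 1 without adult CR replicate 4 of ZT 8. It was between 5 and 9 without aged CR replicate 2 of ZT 0 (9), 3 of ZT 12 (6), 1 or 3 of ZT 16 (5 and 7) or 3 of ZT 8 (6), aged control replicate 2 of ZT 4 (7) or adult control replicate 3 of ZT 16 (7). The same held for adult CR replicate 4 of ZT 0 (9), 5 of ZT 12 (5), 3 or 5 of ZT 16 (5 and 7) or 1 or 3 of ZT 8 (7 and 6).

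The effect of CR was not found to differ between the ages for any single gene. In limma, 0 genes passed, with 282 at an unadjusted p under 0.05, where chance alone gives 669. The genes with the smallest p were Specc1, Mical1, H1f10, Bmyc, Parpbp and Clasrp (adjusted p = 1). As lists, mitosis genes differed in the same direction for 19 of 19 (median 0.24, adjusted p = 2.16e-17, and adjusted p = 0.157 with an estimated correlation), being lower under CR in adult mice and higher in aged mice. Langerhans cell and macrophage markers responded lower in aged mice for 8 of 9 (adjusted p = 4.5e-05, and adjusted p = 0.157 with an estimated correlation), with 0 called and 3 adjusted over the list alone. Cholesterol synthesis responded higher for 15 of 16 (adjusted p = 4.5e-05, and adjusted p = 0.454 with an estimated correlation), with 0 called (0 adjusted over the list alone).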

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

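The tests with array background as a covariate, the comparison with the 4 fibroblast markers, the fits without time point 0 and the phase shift of the core clock were chosen only after results had been seen, while the other tests here were fixed in advance or, for the weighed patterns, before their own result was known.

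In 126 comparisons of the arrays of a group on 1 of 6 measures, 4 found an array far from the others, and chance alone gives about 1 in 20. Replicate 4 of aged CR at ZT 0 had a mean deviation from its group of 0.45, against 0.24 to 0.27 for the others (gap over range 0.831). Replicate 5 of aged CR at ZT 20 lay closer to its group than the others (0.10 against 0.13 to 0.14, gap over range 0.735). The level of Dbp in replicate 3 of aged control at ZT 20 was 8.16, against 5.67 to 6.21 (gap over range 0.782). The level of Per2 in replicate 4 of adult CR at ZT 8 was 7.57, against 8.28 to 8.42 (gap over range 0.835).

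The response to CR differed between aged and adult mice for 7 gene lists in the test of the age by diet interaction with camera, and for 0 of them with an estimated correlation. Mitosis genes responded higher in aged mice for 19 of 19 genes (adjusted p = 2.16e-17, and adjusted p = 0.157 with an estimated correlation). Ribosomal protein genes responded lower for 19 of 19 (median -0.06, adjusted p = 4.24e-06, and adjusted p = 0.441 with an estimated correlation). Langerhans cell and macrophage markers responded lower for 8 of 9 (median -0.15, adjusted p = 4.5e-05, and adjusted p = 0.157 with an estimated correlation). Cholesterol synthesis responded higher for 15 of 16 (median 0.12, adjusted p = 4.5e-05, and adjusted p = 0.454 with an estimated correlation). Oxidative phosphorylation responded lower for 20 of 22 (median -0.11, adjusted p = 0.00621, and adjusted p = 0.839 with an estimated correlation). Autophagy and lysosome genes responded lower for 18 of 20 (median -0.06, adjusted p = 0.015, and adjusted p = 0.636 with an estimated correlation). Inflammation genes responded higher for 11 of 14 (median 0.09, adjusted p = 0.0193, and adjusted p = 0.285 with an estimated correlation).

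Each count of genes was compared with 100 assignments of the same arrays, the real one included. For rhythms the arrays of a condition were assigned to other time points. As many rhythmic genes came from 2 of 100 assignments in adult control (156 genes, highest other 710). They came from 1, the real one, in adult CR (1082 genes, highest other 1), aged control (750, highest other 53) and aged CR (652, highest other 144). Each lies under the limit of 5, uncorrected over the counts tested, which argues against chance, least clearly in adult control. The assignments cannot address the day of collection, since each day served a single time point. For the other counts the arrays were assigned to other conditions within time points. These assignments argue against chance for CR in adult mice (1 of 100, 74 genes, highest other 1) and CR in aged mice (1 of 100, 37 genes, highest other 1). The same holds for the daily curves under CR in aged mice (1 of 100, 12 genes, highest other 1). For the daily curves under CR in adult mice (1 of 100, 7 genes) another assignment gave 6, close to the real count. For age under CR 4 of 100 assignments gave as many (3 genes), just under the limit of 5 and uncorrected over the counts tested, so this argues only weakly against chance. Another assignment gave 2463 genes there, which points to a structure of the samples, as does the 710 above, and its cause was not tested. For a count of 0 every assignment gives as many, so the assignments decide nothing for age on control diet (100 of 100, 0 genes, highest other 2), the interaction (100 of 100, 0 genes, highest other 334) and the daily curves by age (100 of 100, 0 genes, highest other 1). Chance is not excluded for the difference in the number of rhythmic genes between aged and adult control (32 of 100, 594, highest other 1804), adult CR and adult control (19 of 100, 926, highest other 1513) or aged CR and aged control (89 of 100, -98, highest other 2698).

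Adult CR had more rhythmic genes than adult control (1082 against 156), but a test of any difference among the 6 time points called 770 against 534, a ratio of 1.44, and with all arrays in 1 fit the order turned, with 750 against 888. With 3 arrays at every time point the ratio of the counts was 4.62 (296 against 64 genes), which argues against the smaller number of adult control arrays as the whole cause. With array background as a covariate it was 3.63 (1748 against 481), which argues against a background that varies along the day. Chance remains open, since 19 of 100 assignments gave a difference as large, and without time point 0 the counts were 306 and 127. An effect of the diet stays open, as untested.

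In all, 15 genes were lower under CR at both ages, with a median change of -0.49 in adult and -0.47 in aged mice. With array background as a covariate 15 of them stayed past the threshold at both ages, which argues against a difference in background as the whole cause. With the bulge marker score as a covariate 15 did too. The markers in that score moved in both directions under CR in aged mice, from Postn (-0.56 ± 0.15) to Sox9 (0.30 ± 0.17). Their mean is therefore a poor measure of bulge hair follicle cells, and this test decides little. With the fibroblast marker score 15 stayed as well, but that score followed array background within groups (r = 0.882, rho = 0.888, permutation p = 1e-05 for each, the smallest they can give, and r = 0.869 without the 2 arrays farthest in background), so this test decides nothing. Nor does a comparison with the 4 fibroblast markers outside the set and above the 50th percentile of levels, from which the set differed by -0.42 (SE 0.08) in adult and -0.45 (SE 0.09) in aged mice, since Col1a1, Dcn and Col5a1 (mean levels 5.83, 6.04 and 5.95) followed array background too (r from 0.763 to 0.857) and Sparc (9.76) was at -0.17 ± 0.09 in adult mice and fell by 0.43 (SE 0.09) in aged mice. Fewer fibroblasts, fewer bulge hair follicle cells and lower expression within the cells therefore cannot be told apart. An effect of the diet on the cells stays open, as untested.

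The core clock peaked earlier under CR at both ages. If the CR arrays had been collected at shifted times, replication and mitosis genes would have shifted by the same hours, but the core clock shifted by more than the 2 lists together, with a difference of -1.39 h (SE 0.46) in adult mice and -2.38 h (SE 0.40) in aged mice. This argues against a shift of collection as the whole cause, though in adult mice it rests on the mitosis genes (0.01 h, SE 0.96), since the replication genes alone shifted by -2.25 h (SE 0.7), close to the -2.79 h (SE 0.21) of the clock. A smaller shift of collection, of the size seen in the replication and mitosis genes (-1.39 h, SE 0.5, in adult and -1.1 h, SE 0.44, in aged mice), stays open. An effect of the diet or of the hour of feeding, which the labels do not give, also stays open, as untested.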

How the results depend on the processing

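The sex-linked score and array background as covariates, the fits without the 10 arrays of highest background and without time point 0, and the phase of the core clock were chosen after seeing the data. Unless its construction shows it (fewer genes or arrays, a stricter threshold), the cause of a change was not tested. The shift of the core clock under CR kept its direction and its p of 1e-05, the smallest the permutations can give, under every alternative run, between -2.65 and -3.16 h in adult mice and between -3.21 and -3.7 h in aged mice, the fits without single arrays included (-2.7 to -2.93 h and -3.21 to -3.64 h). Of 206 named calls, 73 were lost without time point 0, 41 with the replicate block and 48 on leaving out some single array. With 3 arrays per time group 64 of 155 were lost. Of the 51 named calls that are age or diet effects, 0 changed sign under any alternative. The other 155 are amplitudes and sizes of curve differences, which have no sign, so they could not reverse. Signal near background limits the dim genes, and replicate numbers do not pair the arrays.

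Rhythmic genes, main counts 156 in adult control, 1082 in adult CR, 750 in aged control and 652 in aged CR, moved as follows. A further quantile normalization gave 257 in adult control and 1117 in aged CR. With 3 arrays per time group the counts were 64, 296, 140 and 69, and with array weights (1 of 8 weight fits did not converge) 672, 1705, 4092 and 4353. With all arrays in 1 fit they were 888 in adult control and 998 in aged CR. Normal scores gave 190, 996, 728 and 624 with an ordinary F test, and 0, 620, 0 and 0 with the moderated test, which was replaced after that result had been seen. A test of any difference among the times gave 534 in adult control, and an amplitude of at least 0.25 left 643 in adult CR and 479 in aged control. Blocking on the replicate number gave 395 and the sex-linked score 1018 in aged CR. With array background as a covariate the counts were 481, 1748, 1126 and 1558. Without the 10 arrays of highest background they were 1138 in aged control and 1095 in aged CR, and without time point 0 306 in adult CR, 88 in aged control and 221 in aged CR. Leaving out single arrays gave 87 to 212, 754 to 1379, 345 to 1138 and 347 to 987.

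The difference in rhythmic genes between aged and adult control (594) was 48 with a test of any difference among the times, 331 with an amplitude of at least 0.25, -163 with all arrays in 1 fit, 378 after quantile normalization, 76 with 3 arrays per time group. It was 3420 with array weights, 960 without the 10 arrays of highest background, -39 without time point 0, and 189 to 982 on leaving out single arrays. That between adult CR and adult control (926) was 236 with a test of any difference among the times (770 against 534), 495 with an amplitude of at least 0.25, -138 with all arrays in 1 fit (750 against 888), 232 with 3 arrays per time group, 179 without time point 0, and 598 to 1223 on leaving out single arrays. That between aged CR and aged control (-98) was 153 with a test of any difference among the times, 86 with an amplitude of at least 0.25, 273 with all arrays in 1 fit and -279 with the replicate block. It was -389 with array medians set equal, 482 after quantile normalization, -156 without a filter on dim probe sets. It was 92 with genes above the 50th percentile, -188 with the mean of all probe sets, -17 without the array that stands apart, 261 with array weights, 420 with the sex-linked score, 432 with array background, -43 without the 10 arrays, 133 without time point 0, and -486 to 307 on leaving out single arrays.

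Age on control diet (0 genes) gave 1 gene after quantile normalization, 5 with array weights, and 1 each with condition plus time point, with non-epidermal markers as a covariate and without the 10 arrays of highest background, and 0 to 1 on leaving out single arrays. Age under CR (3 genes) gave 8 after quantile normalization (3 of them higher), 5 without a filter on dim probe sets, 10 with the mean of all probe sets. It gave 761 with array weights, 26 with non-epidermal markers, 1 with a fold change of at least 1.5, 1 with the replicate block, 7 with the sex-linked score, 7 with array background, 19 without the 10 arrays, 0 without time point 0, and 0 to 9 on leaving out single arrays. The diet effect in adult mice (74) was 46 with array medians set equal, 1129 with array weights, 178 with non-epidermal markers, 117 with epidermal differentiation as a covariate. It was 6 with a fold change of at least 1.5, 27 with the replicate block, 147 with array background, 38 without time point 0, and 37 to 1.0e+02 (rounded to 2 digits) on leaving out single arrays. The diet effect in aged mice (37) was 506 with array weights, 999 with non-epidermal markers, 6 with a fold change of at least 1.5, 19 with the replicate block. It was 80 with array background, 106 without the 10 arrays, 57 without time point 0, and 22 to 55 on leaving out single arrays. The interaction (0) was 440 with array weights and 0 on leaving out any array. The correlation of diet effects (0.47) was 0.203 without the 10 arrays, and 0.311 to 0.541 on leaving out single arrays.

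Differences in daily curves under CR in adult mice (7) were 3 with 3 arrays per time group and 12 with array weights, and 7 on leaving out any array. In aged mice (12) they were 28 with the mean of all probe sets, 6 with 3 arrays per time group, 1806 with array weights, 28 without the 10 arrays of highest background, 23 without time point 0, and 11 to 23 on leaving out single arrays. The difference in core clock amplitude between aged CR and aged control (-0.012, not past its test) reversed to 0.004 after quantile normalization, 0.004 with members rhythmic in adult control, 0.025 with 3 arrays per time group and 0.03 without time point 0, and ran from -0.046 to 0.005 on leaving out single arrays. Of the 39 gene list shifts past the threshold, 0 stayed with an estimated correlation.

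The named genes that reversed were none of them past the test. With array weights, Cd3e (0.01), Il2rb (0.02), Col1a1 (0.04) and Dcn (0.01) reversed in the diet effect in adult mice, and Dcn (-0.02) in that in aged mice. Without time point 0, Chac1 (0.11) and Il2rb (0.01) reversed in the diet effect in adult mice, and Lamp1 (0.02) and Wipi2 (0.01) in the interaction. Others were Cd3e without the 10 arrays of highest background (0.02), Rps6 in the age effect on control diet with the mean of all probe sets (-0.01), and Col5a1 in the diet effect in aged mice with non-epidermal markers as a covariate (0.06).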

Other observations

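The comparison of time point 0 with the other times (with its fits without single arrays) and the tests of the fatty acid oxidation list were chosen only after the results that led to them had been seen.

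At ZT 0 the cells of all 4 conditions differed widely from those at the other times (limma, 4 or 5 arrays at ZT 0 in each condition against the mean of the other times). Higher at ZT 0 were 1008 genes in adult control, 301 in adult CR, 490 in aged control and 980 in aged CR, of which 125 were higher in all 4. Lower were 2971, 371, 427 and 1626, of which 147 were lower in all 4. The conditions with the largest counts also held the arrays of ZT 0 that lay farthest from their group, with mean deviations of 0.361, 0.334 and 0.337 for replicates 1, 3 and 4 of adult control and 0.446 for replicate 4 of aged CR. Leaving out single arrays of ZT 0 gave 416 to 1436 higher and 972 to 3610 lower genes in adult control and 722 to 988 higher and 937 to 2045 lower genes in aged CR. It gave 83 to 329 higher and 120 to 400 lower genes in adult CR and 164 to 383 higher and 140 to 296 lower genes in aged control. The largest rises included Abtb2 (3.14 ± 0.41 in adult control, 1.53 ± 0.37 in adult CR, 3.00 ± 0.41 in aged control and 1.99 ± 0.38 in aged CR), the tight junction protein Cldn4 (2.47, 1.85, 2.81 and 2.32), the epithelial factor Ehf (1.98, 1.67, 1.78 and 1.88), the phosphodiesterase Pde4b (2.05, 1.62, 1.73 and 1.91) and Sprr1a, a protein of the cornified envelope (2.06, 1.49, 1.76 and 1.74).

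Among the falls at ZT 0 were those of Tsc22d3 (-3.06 ± 0.22 in adult control, -2.87 ± 0.20 in adult CR, -2.41 ± 0.22 in aged control and -2.69 ± 0.20 in aged CR), Fkbp5 (-2.22, -2.48, -2.14 and -2.36), Zbtb16 (-2.24, -1.28, -1.57 and -1.57), Sphk2 (-2.59, -1.77, -2.35 and -0.94) and Slc43a1 (-1.87, -1.51, -1.77 and -1.29). No gene list was tested at ZT 0. The glucose-responsive Txnip was lower as well (-1.71, -0.98, -1.69 and -1.01), and so were the clock genes Per3 (-1.19, -1.85, -2.14 and -0.95) and Dbp (-1.60, -1.49, -1.57 and -0.89). Each day of collection served a single time point, and no label ties an array to a day, so a batch of that day cannot be separated from ZT 0. Without the arrays of ZT 0, 73 of 206 named calls were lost.

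A hypothesis is that under CR in aged mice the genes of fatty acid oxidation as a group change their time of day, since the fitted peaks of Cpt1a and Eci2 lay 11.6 h and 9.2 h apart and that of the lipid gene Gpam 8.7 h, although Cpt1a (adjusted p = 0.201) and Eci2 (adjusted p = 0.0521) were not called rhythmic in aged mice on control diet. The daily curves of the other 9 tested genes of the fasting and fatty acid oxidation list differed between the diets in aged mice (permutation p = 0.0388, two-sided, 100000 resamples, and adjusted p = 0.0776 over both ages), and their mean vector moved from ZT 20 to ZT 2.9. By the shorter way round the day this mean vector moved later, while the fitted peaks of Cpt1a, Eci2 and Gpam moved earlier. The test takes the distance between the fitted curves, which depends on amplitude as well as on timing. The daily curves of the list may therefore differ between the diets in aged mice, but the test does not pass over both ages. A change of timing common to the list and these genes was not shown. In adult mice the difference over 10 genes did not pass (permutation p = 0.459), and the difference between the ages was not tested.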
